A study of Homo sapiens with 147 samples.

How the data were processed

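The series holds SMART-seq2 libraries of 144 single LNCaP cells, an established human prostate cancer cell line, and 3 bulk libraries made from 1 ng of RNA. Per the labels, cells were arrested at the border of G1 and S phase by a double thymidine block and kept without androgen for about 24 h. One group was taken at that point (0 h), and the others 12 h later without or with 1 nM R1881, a synthetic androgen. The labels assign no cell to a sequencing batch, so no relation could be recomputed within batches. Each group has 48 cells and 1 bulk library. The labels name no separate cultures, so the cells of a group count as cells of 1 culture and each group as 1 sample.

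Per the submitters' processing notes, reads were handled with TopHat, SAMtools, HOMER and DESeq2 on the human build hg19, and no versions are stated. The deposited count table holds expected counts per RefSeq transcript, per the file headers from HOMER over exons on both strands without adjustment for depth. All of its values are multiples of 0.5 and 17.0% are not whole. Because both strands were counted, reads of overlapping or antisense genes cannot be assigned to one of them. The second deposited table holds FPKM values of the same rows, which the authors normalised for transcript length and depth. The authors also deposited 3 tables of differences between groups with a log2 fold change, its lower and upper bound and a p-value per gene, and neither the test nor any adjustment of the p-value is stated.

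Of 50613 transcript rows, 98.5% were matched by RefSeq identifier to 25006 gene symbols with a table of a newer genome assembly, used for names alone. For a gene with several rows, the row with the highest total count was kept. Coordinates are those of the deposited files (hg19, counted from 1). A cell needed at least 100000 reads in genes and at least 2000 genes with a read, and all 144 cells passed. R1881 cells 15 and 23 had near-identical counts, with a chi-square of 1.23 per degree of freedom over 7695 genes against 16.5 for the next closest pair of R1881 cells, and were counted as 1 cell, so that the R1881 group has 47.

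Counts were summed over the cells of a group and scaled by the group total to give CPM. Groups were compared as the log2 ratio of these values, with no test and no p-value, because each group is 1 sample. Intervals are 95% exact Poisson intervals for levels and exact binomial (Clopper-Pearson) intervals for ratios and for shares of cells. The intervals for levels and ratios take each read as an independent count and leave out the spread between cells and cultures. Reads without molecular identifiers are not independent molecules, so these intervals are too narrow even for counting error. The intervals for shares of cells cover the sampling of cells and leave out differences between cultures. A gene without reads in a group took a floor of 3 counts over that group. The bulk libraries were compared in the same way and never pooled with the cells.

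In total, 19 gene lists were written from general knowledge before the data were examined. A list member counted as measured with at least 5 CPM in 1 of the 2 groups compared, and members were sorted into at least 1.5-fold higher, at least 1.5-fold lower, or between. The median log2 ratio of a list was placed among those of 10000 random lists matched on expression in 20 bins, as a description. The named genes also follow a rule fixed in advance. It takes, per comparison, the 10 genes with the largest and the 10 with the smallest log2 ratio among those with at least 20 CPM and a read in at least 0.5 of the cells of the higher group, and with the same direction by summed counts, by the mean of per-cell CPM and in the bulk libraries. XIST and genes of the Y chromosome were left out. The rule adds a fixed set of 12 genes and the 2 highest and 2 lowest members of each list. Some genes that it selects are not reported here.

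A score per cell was the mean of log2(CPM + 1) over the members of a list minus that of expression-matched genes. Scores of the lists G2_M and androgen_induced were compared across cells, in each group on its own. Variation between cells was taken as the coefficient of variation above its trend on expression, for genes with a mean of at least 50 CPM and a read in at least 24 cells.

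The procedure was tested on simulated data, with counts drawn for the real genes from the means, depths and spread between cells measured here. For the comparison of R1881 with untreated cells at 12 h, 10841 simulated genes were measured. Of 50 genes made 2-fold higher all 50 had the right direction and 94% were in the 1.5-fold class. Of 49 genes made 2-fold lower, 48 had the right direction and 95.9% were in that class. Among 10565 unchanged genes, 6.75% fell in the 1.5-fold classes. In the comparisons of the untreated and the R1881 cells at 12 h with 0 h, 9.18% of 10401 and 9.27% of 10397 unchanged genes did. The simulated unchanged genes did not vary together within a cell, and both groups had the same means. These shares therefore leave out lists that vary together, outlying cells and differences between cultures, and are no yardstick for counts of list members.

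Alternatives were equal weight for each cell, TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, all cells or stricter cell filters (at least 500000 reads and 4000 genes), FPKM, cells thinned to 100000 reads, the bulk libraries, no filter on low counts and leaving out each cell in turn. For the scores they also included a pseudocount of 10 and no matched genes. The alternatives were set for the androgen_induced, G1_S and G2_M medians, the correlation and the named genes, and the medians of the other lists were recomputed after their values were seen. After the data were seen, 3 more were added: the near-identical pair counted as 2 cells, the 12 h untreated cells with the most genes left out, and 0 h cell 12, with the fewest genes, left out. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and R 4.3.3. Figures were drawn with matplotlib 3.10.9.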

Results

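Transcripts were measured in 48 single LNCaP cells at 0 h, 48 after 12 h without androgen and 48 after 12 h with 1 nM R1881, of which 47 were counted. The reads in genes per cell ranged from 343042 to about 2519620 at 0 h, from 349484 to about 3073020 in the 12 h untreated group and from 457569 to about 2340580 with R1881. The median cell had reads in 9855 genes at 0 h, in 10373 genes in the 12 h untreated group and in 9869 genes with R1881. The bulk libraries, 1 per group, had about 2924150, 3006780 and 3126350 reads in genes in the same order. There are no replicates of a group, so all differences below are descriptive.

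The R1881 and untreated cells at 12 h were compared to separate the androgen response from the time in culture. Genes known to be switched on by androgen were higher with R1881. KLK3, which encodes prostate-specific antigen (NM_001030047, hg19 chromosome 19, 51358171 to 51364020), was at 55.5 CPM against 1.99 CPM, 27.8-fold higher (95% counting interval 22.9 to 34.2), with an SD between cells of 122 CPM (n = 47) and 6.70 CPM (n = 48). It had reads in 29 of 47 cells (61.7%, interval 46.4 to 75.5) against 12 of 48 (25%, interval 13.6 to 39.6). The neighbouring kallikrein KLK2 (NM_001002231, chromosome 19, 51376689 to 51383823) was 12.7-fold higher. FKBP5, a co-chaperone of steroid receptors, was at 248 CPM against 73.0 CPM (log2 1.77), and the serine protease TMPRSS2 was 3.75-fold higher.

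Of 31 measured members of androgen_induced, 26 were at least 1.5-fold higher with R1881 and none was lower by that much. Their median log2 ratio was 1.41, above all 10000 matched random lists (95% of lists between −0.14 and 0.11), and 2.31 in the bulk libraries. The ion channel gene TRPM8 had reads in 22 of 47 R1881 cells and in 0 of 48 untreated cells at 12 h (exact interval up to 7.40%). It was 149-fold higher with the untreated group set to the floor of 3 counts, a value that depends on this floor and is not a lower bound. The authors' deposited value is 26.5-fold (log2 bounds 4.04 to 5.27). The lowest ratio among the 31 members was that of MAP7D1, at 0.28 in cells and −0.87 in bulk. Other genes among the 10 highest of those with at least 20 CPM and the same direction in bulk were LAMA1, a laminin subunit (log2 3.83), EAF2, an elongation factor partner (3.31), the sialyltransferase gene ST6GALNAC1 (3.24), ALDH1A3, a retinaldehyde dehydrogenase (3.15), the fatty acid elongase gene ELOVL2 (3.13), TUBA3D, a tubulin (3.03, and 2.35 without R1881 cell 34), and the transcription factor gene ZBTB16 (2.76).

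**Figure D1:**
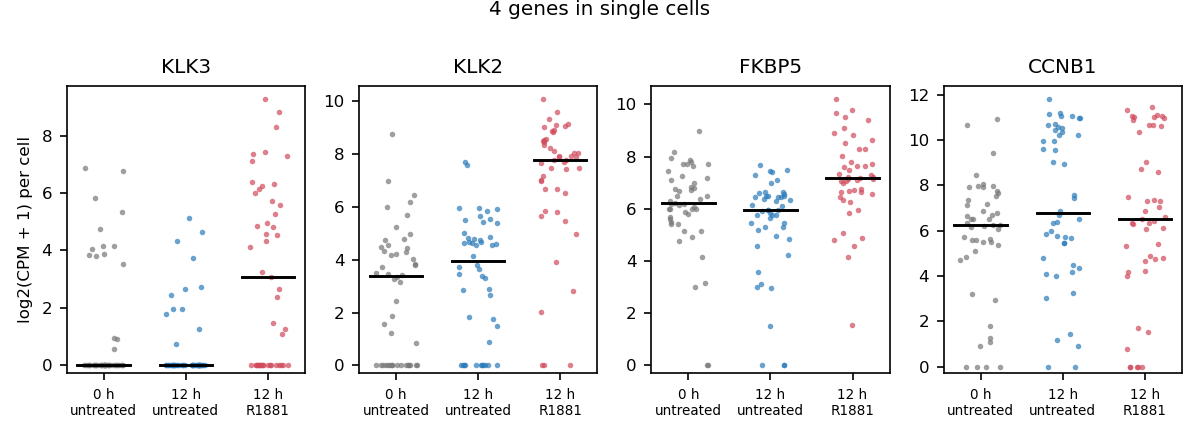
Each point is the log2(CPM + 1) of 1 cell for KLK3, KLK2, FKBP5 and CCNB1, in 48 cells at 0 h, 48 untreated cells at 12 h and 47 R1881 cells, and black lines are medians. The KLK2 median is 7.77 with R1881 against 3.96 without it at 12 h, and the KLK3 median is 3.06 against 0.

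Among the genes lower with R1881, the phospholipase gene PLD1 (NM_002662, chromosome 3, 171318195 to 171528284) was at 2.61 CPM against 22.2 CPM (log2 −3.09). CYP7A1, the rate-limiting enzyme of bile acid synthesis, had a log2 ratio of −2.23, the myelin protein gene PMP22 of −2.17, the ubiquitin ligase gene MID1 of −2.12 and the histone gene H4C3 of −1.86. Others were NFKBIZ (−1.67), RASL11A (−1.54), MYRIP (−1.47) and RFX3 (−1.47). Of 11 measured androgen_repressed genes, 3 were at least 1.5-fold lower and 2 higher, with a median of −0.38. They included CAMK2N1, an inhibitor of a calmodulin-dependent kinase (−2.68), and MET, a receptor tyrosine kinase (−1.98, and −2.87 without R1881 cell 19).

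The G2_M and the measured replication_histones genes were on balance lower with R1881 than without it at 12 h in the cells, while G1_S genes had no stable direction. Of 56 G2_M genes, which peak before and in mitosis, 16 were at least 1.5-fold lower and none higher, with a median of −0.38 (−0.22 without the 12 h untreated cells with the most genes). Cells above the middle of the G2_M score range were 18 of 47 with R1881 and 23 of 48 without it. These shares have overlapping intervals (24.5 to 53.6% and 33.3 to 62.8%). Because G2_M genes vary together across cells, their median depends on which cells were picked. CENPA, a centromeric histone, was at −0.95 and the proliferation marker MKI67 at −0.77, while the mitotic cyclin gene CCNB1 was at 0.021. In the bulk libraries the G2_M median was 1.08, of the opposite sign. Of 44 G1_S genes 6 were lower and none higher, and the median of −0.17 became 0.075 without 12 h untreated cell 4, 0.057 with equal weight for each cell, 0.056 on the FPKM scale and 0.030 in thinned cells. Of 10 measured replication_histones genes, from 22 in the list, 6 were lower (median −0.64). H1-5, a linker histone, was at −2.88, and at −2.02 without 12 h untreated cell 4.

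Genes of protein folding in the endoplasmic reticulum were slightly higher with R1881. The 22 members of ER_stress_secretory had a median of 0.31 (0.20 without the 12 h untreated cells with the most genes), with 4 higher and 2 lower. HERPUD1, of endoplasmic reticulum protein degradation, was 2.11-fold higher, and the stress transcription factor gene ATF4 was at −0.60 (−0.52 without 12 h untreated cell 4). The 28 sterol_fatty_acid_synthesis genes had a median of 0.11, 4 higher and 2 lower. The 20 p53_targets had a median of 0.43, 8 higher and none lower, against −0.32 in bulk. Without R1881 cell 37 this median was 0.087, within the range of 95% of matched random lists (−0.18 to 0.16), so the difference rested on that cell. CDKN1A, which encodes the cell cycle inhibitor p21, was at 2.17, at 1.31 without R1881 cell 37 and at −0.85 in bulk. The growth factor gene GDF15 was at 1.24, at 0.27 without that cell and at −1.39 in bulk.

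The untreated cells at 12 h and at 0 h were compared to follow the cells after release from the block. Genes of mitosis were on balance higher at 12 h in the summed counts of the cells. CCNB1 (NM_031966, chromosome 5, 68462837 to 68474070) was at 705 CPM against 176 CPM, 4.01-fold higher. Its median log2(CPM + 1) per cell was 6.78 against 6.26, and the SDs between cells were 887 and 357 CPM. Cells with high levels thus weigh strongly in the summed ratio. CDC20, an activator of the anaphase-promoting complex, was 4.44-fold higher and the kinetochore motor gene CENPE 4.36-fold higher. Of 56 G2_M genes, 41 were at least 1.5-fold higher and none lower, with a median of 0.83 above all matched random lists. Cells above the middle of the G2_M score range were 23 of 48 at 12 h and 18 of 48 at 0 h. The intervals of these shares overlap (33.3 to 62.8% and 24.0 to 52.6%). Because G2_M genes vary together across cells, this median and its rank depend on which cells were picked. CDK1, the kinase of mitotic entry, was at −0.16. In the bulk libraries the G2_M median was −0.15, with MKI67 at −2.46 in bulk against 1.54 in cells.

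Genes of DNA replication were lower at 12 h without androgen than at 0 h in the cells. Of 44 G1_S genes, 23 were at least 1.5-fold lower and none higher, with a median of −0.61. In bulk the median was −0.33, at percentile 19.0 of matched random lists, with 8 members higher and 19 lower. ORC1, a subunit of the origin recognition complex (NM_004153, chromosome 1, 52838501 to 52870143), was at 12.5 CPM against 36.6 CPM (log2 −1.55). EXO1, an exonuclease of DNA repair, was at −1.07, and at −1.85 without 12 h untreated cell 4. CCNE2, a cyclin of S phase entry, was at −0.86. Of 10 measured replication_histones genes, from 22 in the list, 8 were higher, with a median of 1.12 (0.16 in bulk). The score of this list had correlations of −0.557, −0.136 and −0.339 with the G2_M score at 0 h, in the 12 h untreated group and with R1881. Those of the G1_S score were 0.864, 0.620 and 0.658, so the reads of the histone list did not run with the other cell cycle lists across cells.

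Among genes with at least 20 CPM and the same direction in bulk, the others with the largest ratios in this comparison were PLAAT4, a phospholipase gene (2.32, and 1.11 without 12 h untreated cell 19), GPNMB, a membrane glycoprotein (1.95, 1.06 without 12 h untreated cell 31 and 2.60 without 0 h cell 24), CENPA (1.87), HGD of tyrosine breakdown (1.82), HMMR of the spindle (1.77), HERC5, a ligase for ISG15 (1.69), and GTSE1 of G2 and S phase (1.65). The lowest of these genes was ITPRIP (−1.74), followed by ORC1, UVRAG (−1.25), GPRASP3 (−1.20), TBC1D31 (−1.12), REXO5 (−1.10, and −0.48 without 0 h cell 28), SLC9B2 (−1.08), STOX1 (−1.08), EXO1 and UBR7 (−1.07). Genes that do not meet these conditions went further than some of them, such as KLK3 (−2.36), PMAIP1 (−1.31, and −1.96 without 12 h untreated cell 4), GDF15 (−1.24) and H1-5 (1.92, and 1.06 without the same 12 h untreated cell 4).

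Without androgen, the androgen_induced genes differed little between 12 h and 0 h in the cells, with 6 of 30 higher, 1 lower and a median of 0.062. This median ran from 0.017 with DESeq2 factors to 0.16 without the 12 h untreated cells with the most genes. In bulk it was −0.027, with 8 members higher and 13 lower. KLK3 was at 1.99 CPM against 10.3 CPM in cells (log2 −2.36) and at 0.81 in bulk. The androgen_repressed median was 0.079 with 1 of 10 members higher, and −0.27 in bulk. The sterol_fatty_acid_synthesis median was −0.17 (−0.89 in bulk) with 1 of 28 lower, the ER_stress_secretory median 0.023 with 1 of 22 lower, and the p53_targets median −0.15 with 4 of 20 lower (0.029 without 0 h cell 17). The ER_stress_secretory median changed sign with TMM (−0.0086) and DESeq2 factors (−0.022), with equal weight for each cell (−0.0014), on the FPKM scale (−0.0011) and in thinned cells (−0.043), and the androgen_repressed median with equal weight (−0.0087) and on the FPKM scale (−0.0078). GDF15 was at −1.24, and at 0.44 without 0 h cell 17.

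The R1881 cells at 12 h were also compared with the cells at 0 h, which sets androgen and time together. KLK2 was 8.60-fold higher (15.2-fold without 0 h cell 24) and KLK3 5.40-fold higher. Of 32 androgen_induced genes 28 were at least 1.5-fold higher and 1 lower, with a median of 1.55 (1.66 in bulk). The lower gene was SGK1, a kinase (−0.80, −0.43 without 0 h cell 34, and 2.17 in bulk). Of 11 androgen_repressed genes 1 was higher and 2 lower (median −0.19, −0.11 with equal weight for each cell, −0.072 without 0 h cell 24 and −0.016 with no filter on low counts). TRPM8 had no reads at 0 h and was 161-fold higher at the floor of 3 counts (26.5-fold in the authors' deposited values).

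Of 44 G1_S genes, 34 were lower with R1881 than at 0 h and none higher, with a median of −0.72 (−0.52 in bulk), and RRM2, a ribonucleotide reductase subunit, was at −1.84. Of 56 G2_M genes 28 were higher and none lower, with a median of 0.52 (0.55 in bulk, 0.36 in thinned cells and 0.34 without R1881 cell 36). CCNB1 was 4.07-fold higher. The replication_histones median was 0.47, with 3 of 7 higher and 2 lower (−0.59 in bulk, −0.021 with no filter on low counts and 0.31 without R1881 cell 37). ER_stress_secretory genes had a median of 0.26 with 6 of 22 higher and 2 lower, led by the chaperone genes DNAJC3 (0.99) and HSPA5 (0.88). The p53_targets median was 0.29 with 4 of 20 higher and 1 lower (−0.22 in bulk, and 0.030 without R1881 cell 37), and the sterol_fatty_acid_synthesis median −0.11 with 2 of 28 higher and 3 lower. Under the same conditions, further genes with the largest ratios were LAMA1 (3.89), TUBA3D (3.68, and 3.00 without R1881 cell 34), ST6GALNAC1 (3.62), MAF (3.45), ZBTB16 (3.15), EAF2 (3.04), SLC45A3 (3.03) and PMEPA1 (3.00). At the other end were CDKN1C, which encodes the inhibitor p57 (−3.33, and −2.63 without 0 h cell 25), CYP7A1 (−2.91), PMP22 (−2.13), FUT8 (−2.04), C4orf46 (−1.95), EXO1 (−1.75), PLCH1 (−1.65) and NAPEPLD (−1.63).

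**Figure D2:**
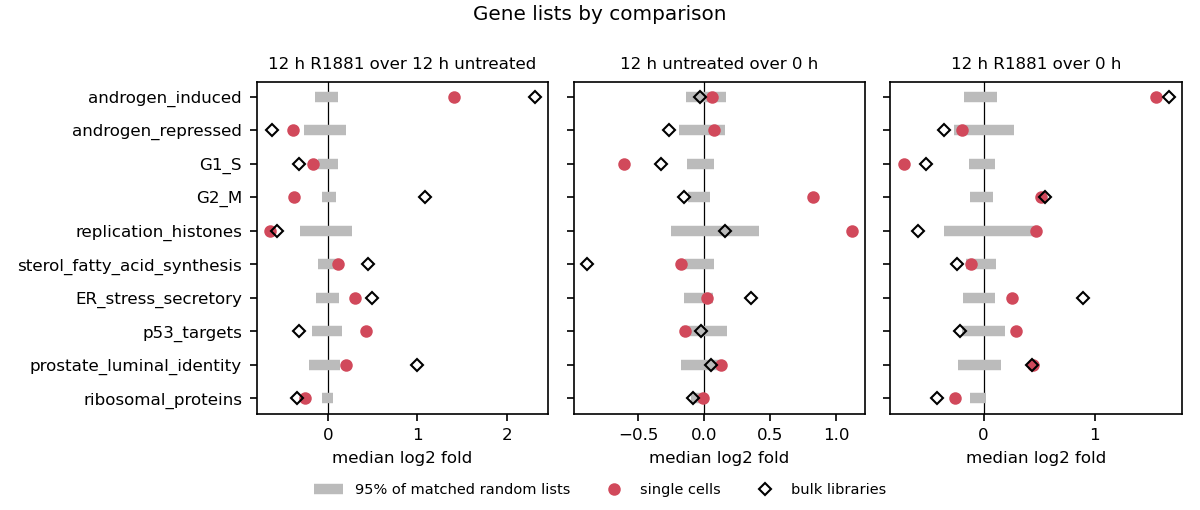
Median log2 ratio of 10 gene lists (rows) in each of the 3 comparisons (panels), in summed single cells (circles) and in bulk libraries (diamonds), with grey bars for 95% of 10000 matched random lists in cells. The androgen_induced medians are 1.41 and 1.55 with R1881 and 0.062 without it, and the G2_M medians of cells and bulk differ in sign in the first and second panels.

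Markers of other cell types were mostly below 5 CPM, with 2 of 8 basal_epithelium, 4 of 13 mesenchymal_or_other_line, 1 of 10 immune, 1 of 10 neuroendocrine and 0 of 5 endothelial genes measured. In the order R1881 over 12 h untreated, 12 h untreated over 0 h and R1881 over 0 h, the medians were −1.01, 0.50 and −0.51 for basal_epithelium, 0.090, 0.43 and 0.52 for mesenchymal_or_other_line, −0.025, 1.06 and 1.04 for immune (CD68 alone), and 0.39, −0.11 and 0.27 for neuroendocrine (ENO2 alone). These lists rest on few genes at low levels and no direction is read from them. With no filter on low counts the basal_epithelium medians were 0.91, 0.50 and 2.02, that of mesenchymal_or_other_line was −0.87 for R1881 over 12 h untreated (−0.015 with equal weight for each cell and −0.19 without R1881 cell 37), and those of immune were 0.63 for R1881 over 12 h untreated and −0.21 for 12 h untreated over 0 h. ENO2 in 12 h untreated over 0 h was at 0.048 with equal weight and 0.39 without 0 h cell 24, and CD68 in R1881 over 0 h at −0.53 in thinned cells. All 15 prostate_luminal_identity genes, 3 of which are also in androgen_induced, were measured with R1881, 7 of them higher than without it at 12 h and none lower, with medians of 0.21, 0.13 and 0.45 in the same order (0.063 for the second in cells with at least 500000 reads and 4000 genes). In bulk these medians were 0.99, 0.055 and 0.44. STEAP1 and STEAP2, genes of the STEAP family, were at 426 and 748 CPM with R1881 against 181 and 404 CPM without it at 12 h.

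Medians in the same order were −0.16, 0.017 and −0.079 for immediate_early_heat_shock, 0.050, −0.14 and −0.14 for hypoxia_glycolysis, and 0.15, −0.25 and −0.18 for apoptosis_damage (−0.54, 0.46 and 0.050 in bulk). The apoptosis_damage median of R1881 over 12 h untreated was 0.021 without R1881 cell 37 and 0.25 without 12 h untreated cell 4. That of immediate_early_heat_shock was −0.059 without 12 h untreated cell 4, −0.034 in cells with at least 500000 reads and 4000 genes and −0.055 with no filter on low counts. The immediate_early_heat_shock median of 12 h untreated over 0 h had no stable sign, at −0.014 with TMM and −0.027 with DESeq2 factors, −0.034 in cells with at least 500000 reads and 4000 genes, and it changed sign on leaving out any of 13 cells. The hypoxia_glycolysis median of R1881 over 12 h untreated was −0.0084 without R1881 cell 39. The immediate_early_heat_shock median of R1881 over 0 h was 0.086 without 0 h cell 17 and 0.16 in thinned cells. In bulk, this list stood at 2.28 in the 12 h untreated library over 0 h and at −1.16 in the R1881 library over it. The reference_genes had medians of 0.050, −0.082 and 0.030, and ribosomal_proteins of −0.26, −0.0057 and −0.26. The first and last of the former were −0.0032 without R1881 cell 38 and −0.013 without R1881 cell 35, and the second of the latter changed sign on leaving out any of 22 cells, so none of these 3 has a direction.

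The authors' deposited tables list 272 genes for the untreated against the R1881 cells at 12 h, 143 for 0 h against 12 h untreated and 303 for 0 h against R1881. For the first pair, 22 androgen_induced genes are in the authors' deposited table, all lower in the untreated cells, and no G2_M or G1_S gene is listed. For 0 h against 12 h untreated, the authors' deposited table has 11 G2_M genes, all lower at 0 h, and 5 G1_S genes, all higher at 0 h. The matched genes had the sign of the summed counts in 249 of 249, 129 of 129 and 289 of 289 cases, as the authors' tables and the sums rest on the same cells, and that of the bulk libraries in 205, 38 and 231.

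The title of the series names cells with more cell cycle transcription and less androgen response, so the scores of both lists were compared across cells. The androgen_induced score had a mean of 0.557 (SD 0.893, n = 47) with R1881, −1.003 (SD 0.318, n = 48) in the 12 h untreated group and −1.18 (SD 0.379, n = 48) at 0 h. The G2_M score split the cells of each group into 2 clusters, parted at the middle of its range after they were seen, with 3, 2 and 1 cells within 0.5 of the middle of the range. Cells above the middle were 18 of 47 with R1881 (38.3%, interval 24.5 to 53.6), 23 of 48 in the 12 h untreated group (47.9%, interval 33.3 to 62.8) and 18 of 48 at 0 h (37.5%, interval 24.0 to 52.6).

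With R1881 the mean androgen_induced score was −0.0705 (SD 0.744, n = 18) in the cells above the middle of the G2_M range and 0.946 (SD 0.752, n = 29) in those below, a difference of −1.02. It lay below all 10000 matched random lists (95% between −0.283 and 0.328). Genes of random lists hardly vary together across these cells (median pairwise Spearman correlation 0.00316, against 0.270 for androgen_induced). Their scores therefore spread less, and this rank partly reflects how coherent the list is. The correlation below does not depend on the scale of the scores, but no lists of like coherence were drawn for its rank. The same difference was −0.174 (percentile 10.3) in the 12 h untreated group and −0.00714 (percentile 50.6) at 0 h, and with 1 culture per group no difference between the groups is read. Within the clusters of R1881 cells, the scores had a Pearson correlation of 0.162 (Spearman 0.135) above the middle and −0.0432 (Spearman −0.0320) below it. A clear relation was thus seen between the clusters and not along them, but 18 and 29 cells over narrowed ranges cannot exclude one there. The planned correlation over all 47 cells, −0.499 (Spearman −0.445), takes in the difference between the clusters, and no test separated a step from a slope. It lay just outside 95% of random lists (−0.494 to 0.555, percentile 2.34). No p-value is given because the cells come from 1 culture. Of 33 androgen_induced genes, 25 had a negative correlation with the G2_M score in R1881 cells. The most negative were those of C1orf116 (−0.581), SORD (−0.568) and ZBTB16 (−0.550). KLK2 (0.0883), FKBP5 (0.0676) and KLK3 (−0.114) had little relation to it, so the difference is not one of every member.

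**Figure D3:**
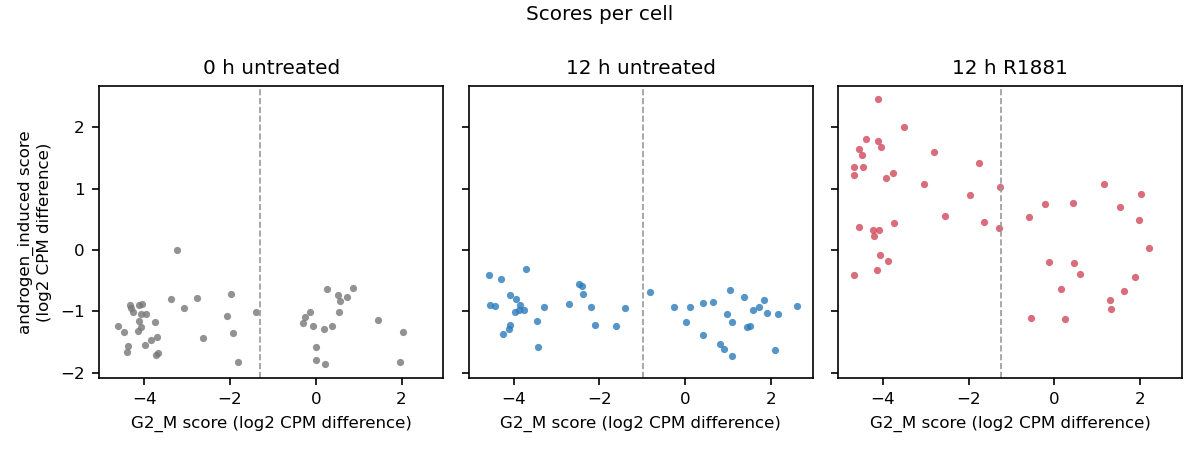
Each point is 1 cell, with its G2_M score on the horizontal and its androgen_induced score on the vertical axis (both as a difference of log2 CPM), in 48, 48 and 47 cells per panel, and dashed lines mark the middle of the G2_M range. With R1881 the mean androgen_induced score is −0.0705 to the right of the line and 0.946 to the left.

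Members of the cell cycle lists varied together across cells. The mean pairwise Spearman correlation of G2_M genes was 0.619 at 0 h, 0.725 in the 12 h untreated group and 0.708 with R1881, and that of androgen_induced genes was 0.00609, 0.0341 and 0.270. The last rests on 21 genes that reached the level needed, against 11 in the untreated groups, so these values do not compare the same genes. Among genes with the largest variation for their level, CDKN1A, IGFBP3, SPON2, CCNB1 and CDK1 were in the 10 of every group. ISG15, an interferon-stimulated gene, had the largest excess in the 12 h untreated group, where 1 cell held 82.0% of its summed CPM.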

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

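The tests of exchanged labels, of library complexity, of G2 or mitosis, of gene number and both tests of cell cycle dependence without androgen were chosen after the results they measure were seen; those of length and level bias, read number, 2 cells in a tube and single list members were set before.

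The 56 G2_M genes stood at a median log2 ratio of 0.83 at 12 h without androgen over 0 h in the cells and at −0.15 in the bulk libraries, a gap of 0.98. Random lists matched on expression and transcript length had a median gap of 0.15, under the bound of 0.24 set in advance, and none of 10000 reached 0.98, which argues against these biases as the whole cause, while 95% of lists ran from −0.16 to 0.50 and leave room for a part. At 2924147 reads the 12 h untreated library had 3.94% more genes than the mean of the others (14035 against 13521 and 13486), which argues against low complexity, and the gap is not only one of G2_M genes, since immediate_early_heat_shock stood at 2.28 in bulk against 0.017 in cells and the ratios of cells and bulk had a correlation of −0.0997 across 10883 genes, which are not independent. What stays open is a difference between the cells picked and the cells that gave the bulk RNA, which 1 library per group cannot address, and an exchange of the 0 h and 12 h untreated bulk libraries, where the bulk median would be 0.15, a value fixed by the −0.15 already seen and so no test. Against an exchange, the bulk median of sterol_fatty_acid_synthesis (−0.89, and −0.17 in cells) has the sign of the cells under the labels given. That of G1_S (−0.33, and −0.61 in cells) does too, but it is at percentile 19.0 of matched random lists in bulk. Since the bulk median of all genes is −0.17, the sign of G1_S says little. Other lists have opposite signs in cells and bulk under the labels given, such as apoptosis_damage (0.46 in bulk, and −0.25 in cells). Only 38 of 129 matched genes listed by the authors for this pair have the bulk sign, and the correlation above is negative, so an exchange is not decided. No biological explanation was tested.

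In the 12 h untreated group, 12 of 48 cells had reads in more genes than any cell of the other groups (over 11165). Thinned to 300000 reads, 11 of the 12 still did, which argues against read number. Their median at that depth was 10759 genes, above the 5th percentile (10162) of sums of 2 other cells of the group, so more than 1 cell in a tube remains a candidate explanation. Their median G2_M score was 3.29 above that of the other 36 cells, so more expressed genes in cells of high G2_M score may account for a part, but cells above the middle of the G2_M range exceeded those below by less than the set exceeded the others (medians 9624.5 and 8960 at 0 h, 9350 and 9242 with R1881, 9710 and 9519 in the other 36 cells), and 2 of the 12 lay below it. Both stay open, and leaving out the 12 cells kept the direction of the G1_S, G2_M and androgen_induced medians that use this group.

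With R1881, cells in the upper cluster of the G2_M score had lower androgen_induced scores. This holds for the list as a set and not for every member, as KLK2, FKBP5 and KLK3 had correlations of 0.0883, 0.0676 and −0.114 with the G2_M score. The correlation of the scores over all 47 cells was −0.499. It was −0.547 with the number of genes detected held fixed and −0.479 or stronger without any single one of 33 list members, which argues against gene number and against 1 gene. With the slope of the 12 h untreated cells taken off it was −0.415, but 9 of the 33 genes had a median under 5 CPM there, where a dependence is poorly measured. For the list as a whole a dependence on the cell cycle without androgen therefore stays open. The score of all 33 genes differed by −0.174 between upper and lower cells of the 12 h untreated group, so the 9 genes were not without a difference. For the other 24 genes the score of the upper cells differed by −0.0585 in the 12 h untreated group against −0.898 with R1881, but cells are not replicates and with 1 culture per group no difference between the groups is read, so it stays open for these genes too. A weaker androgen response in cells of high G2_M score stays a hypothesis, found and tested on the same cells, where the G1_S score had a correlation of only −0.114 with androgen_induced (percentile 34.7 of random lists) but one of 0.658 with G2_M, so no test separates G2 or mitosis from cycling in general, and tubes with more than 1 cell were not excluded.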

How the results depend on the processing

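The alternatives without the 12 h untreated cells with the most genes, without 0 h cell 12 and with the near-identical pair counted as 2 cells were chosen after seeing the data, as were leaving out each cell for the correlation and the medians of lists other than androgen_induced, G1_S and G2_M. No paired analysis was possible because replicate numbers name cells of 1 culture per group and no test was made. All cells passed the filter, so using all deposited cells tests nothing. Ratios are log2 and the cause of each difference was not tested. The androgen_induced medians of 1.41 (R1881 over 12 h untreated) and 1.55 (R1881 over 0 h) kept their sign throughout, at 1.33 and 1.66 in cells thinned to 100000 reads and 2.31 and 1.66 in bulk. The former was 1.30 without the cells with the most genes, and the latter 1.61 with equal weight per cell and 1.61 on the FPKM scale. Leaving out each cell gave 1.36 to 1.502 and 1.48 to 1.66. For 12 h untreated over 0 h, the G1_S median of −0.61 was −0.74 with equal weight, −0.74 as FPKM, −0.65 with DESeq2 factors, −0.71 thinned, −0.52 without the cells with the most genes, −0.33 in bulk and −0.79 to −0.55 leaving out each cell. The G2_M median of 0.83 was 0.74, 0.75, 0.78, 0.71, 0.67, −0.15 and 0.70 to 0.95 in the same order. For R1881 over 12 h untreated, the G1_S median of −0.17 was 0.057 with equal weight, 0.056 as FPKM, −0.13 with DESeq2 factors, 0.030 thinned, −0.32 in bulk and −0.28 to 0.075 leaving out each cell, where 12 h untreated cell 4 alone of 95 changed the sign. The G2_M median of −0.38 was −0.35 with TMM and −0.34 with DESeq2 factors, −0.22 without the cells with the most genes, 1.08 in bulk and −0.49 to −0.27 leaving out each cell. The correlation of −0.499 was −0.486 with a pseudocount of 10, −0.485 in cells with at least 500000 reads and 4000 genes, −0.466 thinned, −0.528 without the 2 cells farthest from the median, −0.404 without matched genes, −0.445 as Spearman's rho and −0.542 to −0.473 leaving out each cell.

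TMM and DESeq2 factors moved the median of all genes by at most 0.044, while bulk moved it by 0.16 for R1881 over 12 h untreated and −0.16 for 12 h untreated over 0 h. Of 150 named values at least 1.5-fold apart, 106 kept their direction in bulk and 44 did not. This count is no measure of agreement, because 56 of the 106 were chosen on having the same direction in bulk, and of the other 94 values 50 kept it (53.2%). Across all measured genes the correlation of cell and bulk ratios was 0.218 for R1881 over 12 h untreated, −0.0997 for 12 h untreated over 0 h and 0.278 for R1881 over 0 h, and genes are not independent replicates. For R1881 over 12 h untreated the bulk values were 3.18 for TOP2A, 2.12 for MKI67, −1.73 for HSD17B6, 0.66 for RRM2, 1.01 for CENPA, 0.29 for CKAP2L, 1.94 for H1-5, 1.17 for H1-4, 0.45 for ELOVL6, −0.65 for DNAJB9, 1.29 for ATF4, −0.85 for CDKN1A, −1.39 for GDF15, −0.39 for SLC2A1, 1.403 for DST and 0.36 for RPL41. For 12 h untreated over 0 h they were 0.81 for KLK3, 0.16 for PCNA, −1.93 for TOP2A, −2.46 for MKI67, −3.36 for MAF, −2.04 for H1-5, −2.36 for H2AC20, 1.52 for HERPUD1, 1.87 for GDF15, 2.66 for FAS, 4.41 for ATF3, 1.91 for PMAIP1, 0.54 for CASP8, −1.78 for DST, −2.01 for FN1 and −2.04 for CD68. For R1881 over 0 h they were −0.34 for MKI67, 2.17 for SGK1, −0.17 for H2BC12, −0.65 for H1-2, 0.59 for DDIT3, 0.29 for ATF4, −1.05 for CDKN1A, −0.60 for GADD45A, 0.90 for ATF3, 0.99 for JUN, 0.26 for PMAIP1 and −0.11 for ACTA2. Apart from these, CD68 (R1881 over 0 h) was at −0.53 in thinned cells and GDF15 (12 h untreated over 0 h) at −1.52 to 0.44 leaving out each cell, the latter without 0 h cell 17, and all others of the 150 kept their direction under every alternative run in cells. Thinning moved 168 of 252 named values outside their counting interval, but it also weights cells more equally, and equal weight at full depth moved 128, so these values do not separate depth from weight. Single cells set several medians: without R1881 cell 37 that of p53_targets went from 0.43 to 0.087 for R1881 over 12 h untreated and from 0.29 to 0.030 for R1881 over 0 h, and without 0 h cell 17 from −0.15 to 0.029 for 12 h untreated over 0 h.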

Other observations

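The interferon list and the values below were chosen after the data were seen. Interferon-stimulated genes were concentrated in single cells. Of 29 such genes measured in the 12 h untreated group, cell 19 had the highest CPM for 16. ISG15 was at 8070 CPM in that cell against a mean of 37.6 CPM in the others, and IFIT1, an RNA-binding antiviral protein, was at 2177 CPM against 9.37 CPM. With R1881, cell 41 was highest for 19 of 33 genes, among them IFI6 with 72.6% and OAS1 with 77.3% of the summed CPM of the group, and cell 3 for 10, among them RSAD2 with 86.4%. At 0 h, cell 24 was highest for 10 of 25, with 53.8% of OAS1. The same 0 h cell had KLK2 at 431 CPM against a mean of 16.5 CPM in the others and the highest androgen_induced score of its group, 0.00798, without added androgen.

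Targets of p53 were also uneven. R1881 cell 37 had the highest CPM for 15 of 20 measured p53_targets, including the ubiquitin ligase gene MDM2 at 1389 CPM against a mean of 141 CPM in the others. In the 12 h untreated group, cell 31 was highest for 8 of 20, and at 0 h cell 17 for 7 of 20, with 61.8% of GDF15.

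With R1881, 10 of 47 cells (21.3%, exact binomial interval 10.7 to 35.7) had an androgen_induced score no higher than the highest 12 h untreated cell, and 8 cells lay within 0.25 of that limit. The score of 12 luminal genes outside androgen_induced was lower in the cells above the middle of the G2_M range in every group. It differed by −0.387 at 0 h, −0.484 in the 12 h untreated group and −0.701 with R1881, at percentiles 1.2, 0.26 and 0.050 of 10000 matched random lists. The correlations of this score with the G2_M score, which do not depend on its scale, were −0.517, −0.617 and −0.684. They lay at percentiles 1.8, 1.28 and 0.3 of random lists, which were not matched on coherence. Single genes had a negative correlation with the G2_M score in 9, 11 and 10 of 12 cases, and that of EPCAM was positive in every group (0.196, 0.0618 and 0.294). Genes outside androgen_induced are not free of androgen, as the deposited table of the authors has KRT19, STEAP1 and STEAP2 lower without R1881 in both comparisons with it.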
